A study of Oryza sativa Japonica Group with 18 samples.

How the data were processed

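Transcript levels were measured in 18 samples of rice, from root and shoot of wild type, a gi knockout and a pho2 knockout, with 3 samples in each of 6 groups. The groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit, made into biotin-labelled cRNA and hybridised to Affymetrix rice arrays. The deposited values are intensity on a linear scale, 1 per probe set and array, and MAS5 is named in the submitters' processing notes (its version and settings are not given in the sources used here). MAS5 scales each array to a common trimmed mean, and the trimmed mean of every column was close to 500 when tested on the values. Detection calls were not used here. No array duplicated another, with 0 pairs of identical columns, and 0 columns of per-sample values were left unused. Arrays have no read depth, and their number limits the precision.

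The table holds 57381 probe sets, of which 123 Affymetrix controls were left out of all tests. Values were used as deposited, as log2(value + 16). Because of the pseudocount of 16, log2 changes of dim probe sets are understated. For each tissue the 9 arrays were fitted together in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, so that 3 genotypes share an estimate of the spread. Probe sets with a mean over the fitted arrays under the 40th percentile were left out, which leaves 34355 in each fit. Tests were two-sided, p-values were adjusted by the method of Benjamini and Hochberg, and a probe set was called at an adjusted p under 0.05. The limma adjusted p in the text is this value. Compared were pho2 with WT, gi with WT and pho2 with gi in each tissue. The difference of each mutant's effect between root and shoot, and WT root against WT shoot, were tested in a fit of all 18 arrays with 6 group means. A log2 change is the mutant less WT, and a tissue difference is the effect in root less that in shoot. Levels are means ± SD of the deposited signal, with n = 3.

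Probe sets were named through the array's platform annotation and a table of rice genes. Of the probe sets, 22436 had 1 gene, 95 had several and were not named, and the rest had none in these tables. The 17905 genes include 2449 with a name other than a locus number, reached by 3182 probe sets. Gene names are those of the tables, so a name states what the tables call a gene. Some genes have more than 1 probe set, and these can differ. SPX5 is given by the probe set with the smaller p (2.5) in its own sentence, and by the brighter probe set (2.14) in list counts, RAB21 in pho2 shoot gave 5.22 and 3.20, and HAK1 in gi shoot -1.90 and -1.39. PHO2 carries no name in these tables and was not analysed here, nor were purple acid phosphatases, for which no usable names were found.

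Gene lists were compiled for Pi transporters of the PHT1 family, SPX domain genes, Pi signalling, the Pi starvation response, nitrogen uptake and assimilation, iron acquisition, the circadian clock, flowering time, diterpenoid phytoalexins, root markers, jasmonate, WRKY factors, defence proteins and chitinases, LEA proteins and dehydrins, heat shock proteins, aquaporins, photosynthesis, ribosomal proteins, histones and replication, starch and sucrose metabolism, glycerolipid remodelling and class III peroxidases. The themes, the members of the lists up to root markers other than the SPX domain list, the design, the named-gene rule and the processing alternatives were set before the data were examined. Of 121 genes on those lists, 73 were used, 32 had no name match, 13 were named but not paired with a probe set, and 3 lay on another chromosome or were ambiguous. Because the tables hold no descriptions, the other lists were filled by patterns in gene names, in place of the descriptions foreseen, after array quality, control probe sets, the numbers of calls and the values of GI, LHY and PRR1 had been seen. The ribosomal list was foreseen for cytosolic proteins, but names do not tell these from plastid ones. Lists for auxin, the cell cycle, protein folding in the endoplasmic reticulum, expansins and cellulose synthases, metal transport, potassium transporters and sugar transport were added at that stage. Lists with at least 5 tested genes were tested against all other genes with camera from limma, with a preset correlation of 0.01 between genes and the brightest probe set per gene. Camera p-values were adjusted over the lists of a comparison, apart for the added lists. Camera was also run with the correlation estimated from the residuals, and with it 0 lists were called in any mutant comparison. At an unadjusted p under 0.05, 2 of 21 lists passed with that correlation in pho2 root and 0 of 18 in pho2 shoot.

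Named in the text are GI on every array; the 6 highest and 6 lowest log2 changes of each mutant against WT among called probe sets with 1 named gene and no overlap between the groups; up to 4 called members of each list with the smallest p, or up to 2 as values; the 5 probe sets called in both mutants with the largest smaller change, and up to 5 with opposite signs; and the 4 highest and 4 lowest of the other comparisons. A gene named outside this rule was chosen after its values were seen.

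The computations were tested on simulated data with the means and spreads of the real arrays, over 34355 probe sets. In 20 simulated sets each, 5.8% of calls were false for pho2 against WT in root and 6.2% in shoot. Of probe sets changed 4-fold, 94.8% were called in root and 82.4% in shoot. A first set called 74.6% of 2-fold changes in root and 47.8% in shoot, and 14.9% and 16.4% of changes of 0.5 on the log2 scale. In it, 67 probe sets were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. These are far fewer than were called in the real comparisons. The adjusted threshold depends on that number, so the rates do not give the recovery in the real data. The recovery of 4-fold changes required at first was above what the first shoot set gave (86.4%), and this requirement was lowered after the 20 sets had been examined. To judge overlap between comparisons that share the WT arrays, 100 unchanged pairs of groups were simulated, and the covariance of their log2 changes was taken.

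Counts of calls were recomputed with pseudocounts of 1 and 64, with no filter or a filter at the 60th percentile, with quantile normalization, with each array centred on its median, with array weights, without the intensity trend, with the 6 arrays of a comparison or all 18 in a fit, with the replicate number as a block, with a 2-fold minimum, and without each array in turn. Single genes, shared calls, tissue differences and lists were recomputed with part of these, and lists also with the mean of a gene's probe sets. After seeing the data, the WT arrays were also split 1 and 2 between the mutants, the ribosomal list was tested without CL18 and CL27, GI in pho2 was tested in a fit of the 6 pho2 and WT arrays, and shared calls were counted with each group as the reference. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.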

Results

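Transcript signals of rice (cultivar Nipponbare, Japonica) were measured on 18 Affymetrix rice arrays. Root and shoot were sampled from wild type (WT) and from knockouts of GI or PHO2, with 3 arrays in each of the 6 groups. GIGANTEA (GI) is a clock-associated protein that acts on flowering time, and PHO2 is a ubiquitin-conjugating enzyme that restrains phosphate (Pi) uptake and its loading into the shoot. The title of the series links both genes to flowering time and Pi balance. The comparisons therefore asked which transcripts moved when either gene was lost, and whether the same transcripts moved in both mutants. Plants were 21 days old, after 2 days of germination and 19 days in hydroponic culture with sufficient Pi under a 12 h photoperiod. The sample details used here give no hour of harvest. A difference in hour between groups was not tested and may enter the changes of clock genes. Every array had the same trimmed mean of 500, and array medians lay between 52.3 and 70.2 signal units. Replicates correlated at 0.9824 to 0.9856 in root and 0.9535 to 0.9712 in shoot (Pearson's r across probe sets of log2 signals, genes not being independent replicates). The labels do not say whether replicates came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

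GI transcript was low on each array of the gi mutant. In root, the signal of the GI probe set was 1.36, 1.71 and 2.19 on the gi arrays, against 7236, 7007 and 7393 on the WT arrays and 8200, 8030.1 and 7920.1 on the pho2 arrays. In shoot, it was 44.6, 5.43 and 14.6 on the gi arrays, against 11521, 9868 and 10889 in WT and 6835, 8088 and 7142 in pho2. GI was called lower in gi root (log2 change -8.67, SE 0.066, limma adjusted p = 3.21e-13) and in gi shoot (-8.30, SE 0.271, limma adjusted p = 6.33e-09). In pho2, GI was not called in root (0.16, SE 0.066, limma adjusted p = 0.136) or in shoot (-0.55, SE 0.271, limma adjusted p = 0.164), in fits that share the spread of the gi arrays. All 3 pho2 arrays lay above all 3 WT arrays in root and below them in shoot. In a fit of the 6 pho2 and WT arrays alone, chosen after seeing the data, GI was called lower in pho2 shoot (-0.55, SE 0.089, limma adjusted p = 0.00129, 0.00129 to 0.475 over its alternatives) and not called in root (limma adjusted p = 0.0752, 0.0434 to 0.773). It was also called in shoot with a pseudocount of 64 (0.0113) and with array weights (0.0409), and in root after quantile normalization (0.0434). The transcript of PHO2 itself was not analysed here, so the pho2 labels were not checked in this way.

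**Figure D1:**
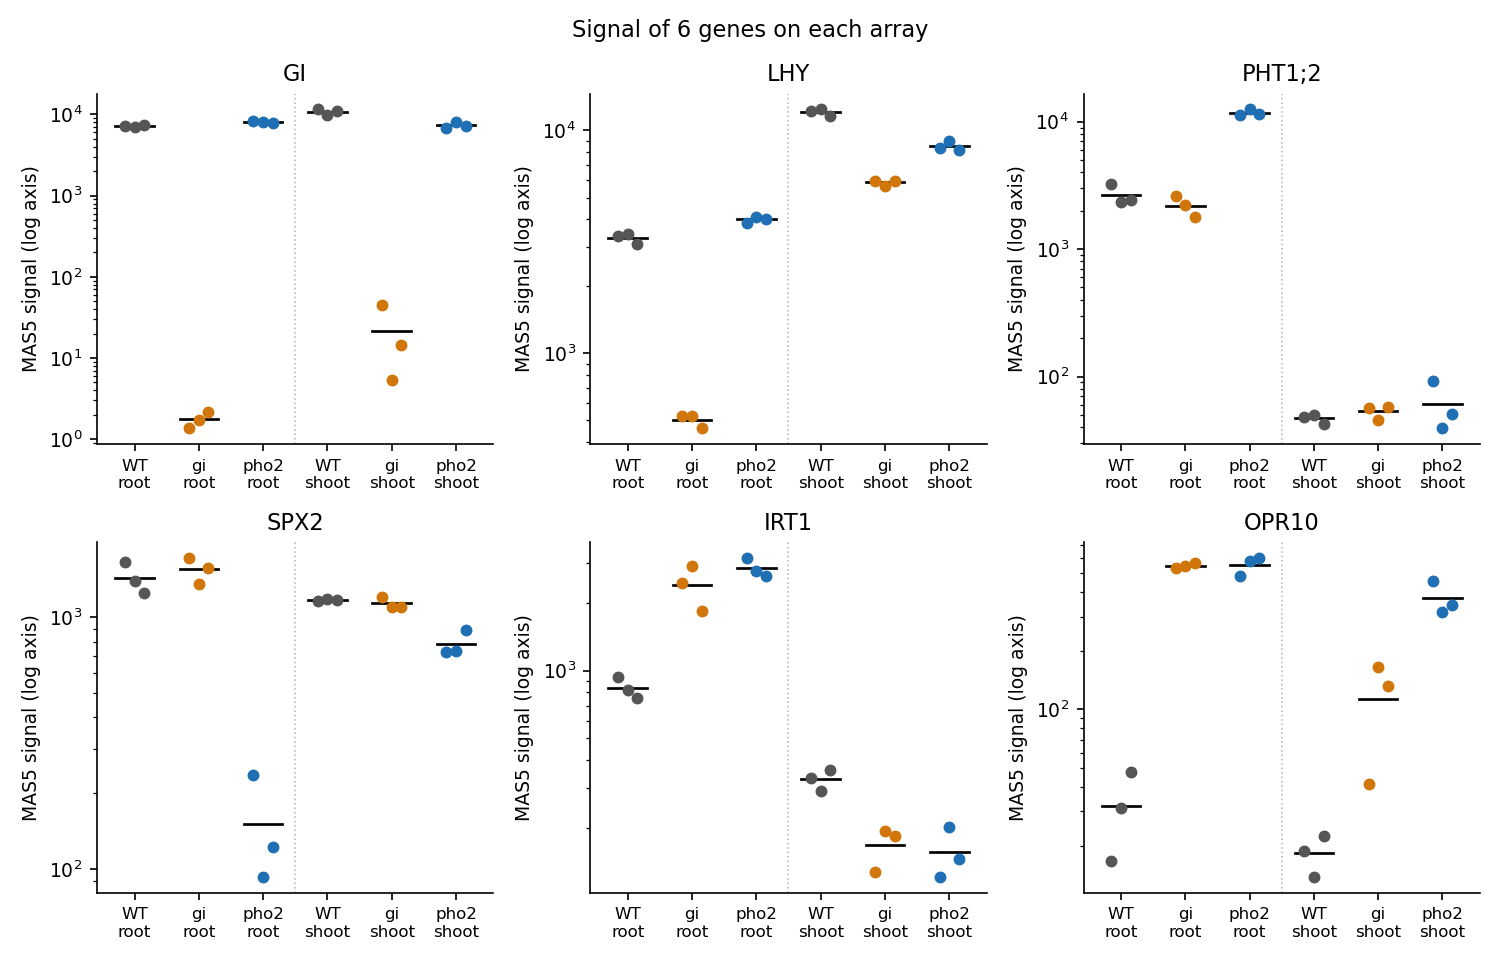
MAS5 signal (intensity, log axis) of GI, LHY, PHT1;2, SPX2, IRT1 and OPR10 in the 6 groups of genotype and tissue, with a point for each array and a bar for the mean of 3. GI lies at 1.75 in gi root against 7212 in WT root, PHT1;2 at 11794 in pho2 root against 2672 in WT root, and OPR10 at 554 and 548 in the pho2 and gi roots against 31.8 in WT root.

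Of 6 phosphate transporters of the PHT1 family tested, 3 were called higher in pho2 roots and 3 were not called. PHT1;2, a Pi transporter that is induced when Pi is scarce, reached 11794 ± 594 signal units (SD, n = 3) against 2672 ± 510 in WT (log2 change 2.15, SE 0.144, limma adjusted p = 3.64e-05). PHT1;1, a Pi transporter active under sufficient Pi, reached 4646 ± 410 against 2320 ± 94.9 (0.99, limma adjusted p = 8.14e-05). PHT1;4 rose by 1.13 (SE 0.153, limma adjusted p = 0.0016), while PHT1;8 (0.23) and PHT1;3 (0.27) were not called. The counts, 3 higher and 0 lower, were the same when adjusted over the list alone (camera adjusted p = 0.00729, but adjusted p = 0.103 with no filter and adjusted p = 0.236 with an estimated correlation). The SPX genes, which encode proteins that bind inositol pyrophosphates and act on PHR transcription factors, went in both directions. SPX5 rose by 2.5 (SE 0.226, limma adjusted p = 0.000218) and SPX1 by 1.25 (SE 0.182, limma adjusted p = 0.00222), whereas SPX2 dropped by 3.20 (SE 0.255, limma adjusted p = 8.85e-05), from 1429 ± 212 to 151 ± 75.4. Of 7 genes with an SPX domain, 2 rose and 1 fell, and of 7 genes of the Pi starvation response, which share members with both lists, 4 rose and 1 fell, with the same counts when adjusted over the list alone. The camera test of the starvation response list gave an adjusted p of 0.0559 as deposited, 0.0452 after quantile normalization and 0.0264 after median centring, and adjusted p = 0.417 with an estimated correlation. Among 6 genes of Pi signalling only PHR3, a MYB-type regulator, rose (0.77, limma adjusted p = 0.0441, 0.0175 to 0.225 over its alternatives). That call ended in 10 of 14 alternatives, and the change was 0.46 without pho2 root replicate 1. MGD2, a galactolipid synthase, rose by 1.11 (limma adjusted p = 0.0449, 0.0303 to 0.124), a call that ended in 11 alternatives, with 0.71 without pho2 root replicate 1 and 0.68 with a pseudocount of 64.

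Of 9 genes of nitrogen uptake and assimilation, 4 were called lower in pho2 roots and 5 were not called. AMT1;2, an ammonium transporter, dropped by 1.97 (SE 0.256, limma adjusted p = 0.00132), from 8009 ± 429 to 2146 ± 844. NRT2.2, a high-affinity nitrate transporter, dropped by 1.79 (SE 0.161, limma adjusted p = 0.000213), AMT1;1 by 0.88 and GS2, the plastid glutamine synthetase, by 1.0. The counts, 0 higher and 4 lower, were the same when adjusted over the list alone (camera adjusted p = 0.0233, but adjusted p = 0.236 with an estimated correlation). Of 23 ribosomal proteins, 0 were called higher and 16 lower, or 19 lower when adjusted over the list alone (camera adjusted p = 1.37e-06, but adjusted p = 0.379 with an estimated correlation). Examples were RPS10-1 (-0.55, limma adjusted p = 0.00237), RPL39C (-0.32) and RPL9 (-0.29), and the number of members called lower was 10 after quantile normalization. Of 22 genes of starch and sucrose metabolism, 2 rose and 6 fell, also when adjusted over the list alone. TPP4, a trehalose phosphate phosphatase, dropped by 1.37 (limma adjusted p = 8.14e-05) and SPS3, a sucrose phosphate synthase, by 0.47 (limma adjusted p = 0.00224).

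The highest and lowest named genes of pho2 roots came from several pathways. OPR10, named for oxophytodienoate reductase, a step of jasmonate synthesis, reached 554 ± 61.8 against 31.8 ± 15.5 in WT (3.62, SE 0.209, limma adjusted p = 1.41e-05). LOGL3, of the cytokinin-activating LOG family, rose by 2.55 (SE 0.443, limma adjusted p = 0.00503). Its signal was 48.6 ± 25.9 in WT root, 358 ± 143 in pho2 root and 2656 ± 314 in WT shoot. APG8D, an autophagy ATG8 protein, was called higher by 3.43 (SE 1.02, limma adjusted p = 0.046), but the call ended in 7 of 14 alternatives (7.88e-07 to 0.151, with 0.151 without WT root replicate 1), and WT signal was 193 ± 326. GLO1 was called higher by 2.19 (SE 0.617, limma adjusted p = 0.0377), which ended in 6 alternatives (0.00201 to 0.126, with 0.126 without WT root replicate 1). GLO1 signal was 50.5 ± 32.3 in WT root, 290 ± 155 in pho2 root and 18910 ± 613 in WT shoot. SWEET1B, also bright in WT shoot (2253), lay at 3.42 in WT root and 3.39 in pho2 root. Shoot tissue in the root samples was not tested. GLT2 dropped by 3.47 (SE 0.407, limma adjusted p = 0.000847), a value of -5.31 with a pseudocount of 1 and -2.15 with 64, since its pho2 signal was 16. EXPB18, a beta-expansin of cell wall loosening, dropped by 2.89 (SE 0.629, limma adjusted p = 0.0132), and ADF-9, an actin-depolymerizing factor, by 2.72 (SE 0.544, limma adjusted p = 0.00927). ILL3, named for auxin conjugate hydrolases, dropped by 2.85 (SE 0.685, limma adjusted p = 0.0201, 0.00693 to 0.0694 over its alternatives). Its call ended without WT root replicate 1 (0.0694) or replicate 2 (0.0521). GLU6 dropped by 2.31 (SE 0.667, limma adjusted p = 0.042, 0.0134 to 0.105 over its alternatives). Its call ended in 5 of them, and the change was -1.45 without pho2 root replicate 1.

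In pho2 roots IRT1, the ferrous iron transporter of the root, reached 2861 ± 276 against 838 ± 94.1 (1.75, SE 0.152, limma adjusted p = 0.000153), and it alone rose among 10 iron acquisition genes (camera adjusted p = 0.327). Of 31 jasmonate genes, 8 rose, 0 fell and 23 were not called, or 9 rose when adjusted over the list alone (camera adjusted p = 0.0559, 0.0312 after quantile normalization and 0.0396 after median centring, where 4 rose, and adjusted p = 0.445 with an estimated correlation). CM-LOX2, a lipoxygenase, rose by 1.12 (limma adjusted p = 0.00699). Of 6 clock genes 2 rose and 0 fell, or 5 when adjusted over the list alone (camera adjusted p = 0.0287, but adjusted p = 0.379 with an estimated correlation, 0.0647 without pho2 root replicate 1, and 0.0178 and 0.0516 after quantile normalization and median centring). PRR95, a pseudo-response regulator, rose by 0.57 (limma adjusted p = 0.00443). LHY, a morning MYB factor, rose by 0.27 (limma adjusted p = 0.033, 0.0108 to 0.2 over its alternatives), a call that ended in 7 of them. Of 11 genes of defence proteins and chitinases, Chib3H-a, a chitinase, alone rose (1.74, limma adjusted p = 0.00107). Among 20 heat shock proteins, 4 rose and 2 fell, or 4 and 3 when adjusted over the list alone. hsp17.9 rose by 1.12 and HSP23.2 dropped by 1.18 (limma adjusted p = 0.000381), and after median centring 1 rose and 3 fell. Dhn1, a dehydrin, dropped by 0.67 (limma adjusted p = 0.0029, but 0.161 in a fit of all 18 arrays, 0.00128 to 0.161 over its alternatives) as the only called gene of 5 late embryogenesis abundant (LEA) genes, whose median was 0.09 and mean 0.22 while the camera direction was down, or up after median centring. Of 22 aquaporins, 2 fell, among them PIP2;5 (-0.82, limma adjusted p = 0.0087). Called members were 1 of 12 flowering genes, 2 of 6 WRKY factors, 1 of 8 diterpenoid phytoalexin genes, 1 of 5 glycerolipid genes and 1 of 14 histone and replication genes, all of them higher, and 0 of 8 photosynthesis genes and 0 of 4 peroxidases (limma). With adjustment over the list alone, these became 0 flowering genes, 3 WRKY factors, 0 diterpenoid genes, and 2 glycerolipid genes higher and 1 lower. After median centring 0 genes of the flowering, WRKY, diterpenoid and glycerolipid lists were called (limma). Of 7 root markers 2 fell and 0 rose, with a median of 0.00 and a mean of -0.32.

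In total, 5438 of 34355 probe sets (15.8%) were called in pho2 roots, 2735 higher and 2703 lower, and 820 of them changed by at least 2-fold. The 3 pho2 arrays lay all above or all below the 3 WT arrays for 5413 of the called probe sets and for 35.1% of all tested, where chance gives 10%. After median centring 37.8% of calls were higher, against 50.3% as deposited. Without pho2 root replicate 1, WT root replicate 1 or WT root replicate 2, the count was 3416, 3385 or 3459. The 3'/5' log2 signal ratio of GAPDH, which RNA quality can move, was 2.23 ± 0.13 in pho2 root and 1.69 ± 0.23 in WT root (SD, n = 3), beside the called ribosomal protein and jasmonate genes. That of cyclophilin was 1.071 ± 0.076 and 1.178 ± 0.065. Among controls for added RNA, the ratio of Bs-dap was 1.885 ± 0.058 in pho2 root and 1.61 ± 0.01 in WT root. That of Bs-thr was 2.331 ± 0.138 and 2.337 ± 0.162. The ratio of GAPDH alone therefore does not show a difference in quality of the rice RNA.

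Genes called in gi roots included clock genes, with no hour of harvest given in the sample details used here. LHY dropped from 3299 ± 192 to 501 ± 35.2 (-2.68, SE 0.074, limma adjusted p = 2.62e-08). PRR1, a pseudo-response regulator of the evening, rose by 1.26 (SE 0.091, limma adjusted p = 6.52e-05) and PRR95 by 1.32 (SE 0.096, limma adjusted p = 6.62e-05). Of 6 clock genes, 2 rose and 2 fell, GI itself among the latter, or 3 and 2 when adjusted over the list alone. Their median was 0.06, or -0.04 after median centring, and their mean -1.44, with a camera direction of down (camera adjusted p = 0.411). BBD1, a bifunctional nuclease, reached 1478 ± 325 against 114 ± 8.91 (3.50, SE 0.175, limma adjusted p = 4.22e-06), and SAPK9, an osmotic stress-activated SnRK2 kinase, 1951 ± 297 against 292 ± 29.6 (2.67, SE 0.13, limma adjusted p = 3.4e-06). OPR10 rose by 3.61 (limma adjusted p = 1.22e-05), Rictpi2, named for a cytosolic triose phosphate isomerase, by 2.02 (limma adjusted p = 2.27e-05) and HAK4, a potassium transporter, by 2.45 (SE 0.336, limma adjusted p = 0.00539). LOGL3 rose by 2.11 (limma adjusted p = 0.0396, 0.00346 to 0.113 over its alternatives), a call that ended in 7 of them, among them without gi root replicate 2 (0.113). At the lower end lay eIF-4G, a translation initiation factor (-1.33, SE 0.107, limma adjusted p = 0.000151), TIP1, a tonoplast aquaporin (-1.52, limma adjusted p = 0.00295), 20ox2, a gibberellin oxidase (-1.39, limma adjusted p = 0.00426), and BHLH172 (-1.50, limma adjusted p = 0.0498, 0.0242 to 0.178 over its alternatives). The call of BHLH172 ended in 8 alternatives, and its change was -0.94 with a pseudocount of 64.

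Phosphate genes were not called in gi roots. PHT1;2 changed by -0.28 (limma adjusted p = 0.377), PHT1;4 by -0.48 (0.151), PHT1;8 by -0.38 (0.152), PHO1;2, a Pi exporter to the xylem, by -0.20 (0.121) and SPX5 by -0.14 (0.822). With adjustment over the list alone, 2 of 6 PHT1 transporters, 1 of 7 SPX domain genes and 1 of 6 Pi signalling genes fell, and 0 of 7 starvation response genes passed. IRT1 rose by 1.48 (SE 0.152, limma adjusted p = 0.000945), to 2400 ± 535, the only called gene of 10 in iron acquisition. MADS56, a flowering regulator of the SOC1 type, rose by 0.80 (limma adjusted p = 0.0117, 0.000482 to 0.0553 over its alternatives), alone among 12 flowering genes, where 3 passed when adjusted over the list alone. Its call ended without WT root replicate 1 (0.0553), without gi root replicate 2 (0.0532) and after median centring (0.0528). CH16, a chitinase, rose by 1.07 (limma adjusted p = 0.00313, but 0.132 in a fit of all 18 arrays, 0.000971 to 0.132 over its alternatives) as 1 of 11 defence genes, where after quantile normalization or median centring 1 rose and 1 fell. Of 22 aquaporins 1 rose and 2 fell, or 1 and 4 when adjusted over the list alone, TIP4-1 by 0.82 (limma adjusted p = 0.00272). Of 31 jasmonate genes 2 rose, of 22 starch and sucrose genes 2 fell, and 1 of 20 heat shock proteins, 1 of 7 root markers and 1 of 8 photosynthesis genes fell. PSAG, the photosystem I subunit G, was that photosynthesis gene (-0.63, limma adjusted p = 0.043, 0.00532 to 0.137 over its alternatives, ended in 8). The other 7 photosynthesis genes had positive values, the list median was 0.88, and 4 passed higher when adjusted over the list alone. Shoot tissue in the root samples was not tested as a source of these values. No member was called among 9 nitrogen genes, 23 ribosomal proteins, 6 WRKY factors, 5 LEA genes, 8 diterpenoid genes, 5 glycerolipid genes, 14 histone and replication genes and 4 peroxidases (limma). Adjusted over the list alone, 1 LEA gene and 1 diterpenoid gene were higher, 1 nitrogen gene was lower, and 3 jasmonate genes were higher. Defence genes, heat shock proteins and root markers each had 1 higher and 1 lower.

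Of 34355 probe sets, 782 (2.3%) were called in gi roots, 401 higher and 381 lower, of which 281 changed by at least 2-fold. All 782 had the 3 gi arrays on one side of the 3 WT arrays, as did 21.7% of the probe sets tested, where chance gives 10%. After median centring, which moved the median of all log2 changes from 0.03 to -0.07, 33.4% of calls were higher, against 51.3% as deposited. The count was 368 without gi root replicate 2, 313 without WT root replicate 1 and 468 without WT root replicate 3. Of 21 lists tested 0 were called (camera), 7 had an unadjusted p under 0.05, and the jasmonate list came closest (adjusted p = 0.0524, but adjusted p = 0.642 with an estimated correlation), with 0.0146 and 0.0121 after quantile normalization and median centring.

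A direct comparison of the mutants in root named both phosphate and clock genes. PHT1;2 was higher in pho2 than in gi by 2.43 (limma adjusted p = 1.87e-05), SPX5 by 2.37 (limma adjusted p = 0.000509) and LHY by 2.95 (limma adjusted p = 1.96e-08). SPX2 changed by -3.32 (limma adjusted p = 0.000122), BBD1 by -3.01 and SAPK9 by -2.23 (both limma adjusted p = 1.69e-05). GLT2 changed by -2.25 (limma adjusted p = 0.0116), or -3.99 and -1.18 with pseudocounts of 1 and 64. The PHT1 list was higher in pho2, with 4 of 6 members called (camera adjusted p = 1.2e-05, but adjusted p = 0.085 with an estimated correlation), and the ribosomal protein list lower, with 6 of 23 (camera adjusted p = 1.2e-05, but adjusted p = 0.412 with an estimated correlation). The starvation response list was higher (camera adjusted p = 0.035, but 0.0517 after median centring and adjusted p = 0.412 with an estimated correlation). In total 2591 probe sets were called (7.5%), 1343 higher and 1248 lower in pho2, and 65.7% of calls were higher after median centring against 51.8% as deposited. The count was 1071 without pho2 root replicate 1, 1471 without pho2 root replicate 2, 1149 without gi root replicate 1 and 1384 without gi root replicate 2.

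Many root calls were shared by the mutants. OPR10 rose by 3.62 in pho2 and 3.61 in gi, Rictpi2 by 1.51 and 2.02, and IRT1 by 1.75 and 1.48. CM-LOX1, a lipoxygenase, rose by 1.65 and 1.60, but its gi call (limma adjusted p = 0.0236, 0.0126 to 0.168 over its alternatives) ended in 7 of them, and its pho2 call (limma adjusted p = 0.00588, 0.000135 to 0.0569) in a fit of all 18 arrays (0.0569). Of the 782 probe sets called in gi roots, 518 (66.2%) were also called in pho2 roots in the same direction and 12 in the opposite direction, LHY among the latter. Independent lists of these sizes would share 61.9 in each way. With pho2 in place of WT as the common reference, WT and gi roots shared 1762 calls in the same direction and 30 in the opposite. With gi as the reference, WT and pho2 roots shared 188 and 59. Control probe sets for ribosomal RNA were brighter in WT root than in both mutants, the 28S probe set at 9301 ± 1439 against 4903 ± 174 in gi and 5705 ± 493 in pho2, and the 25S probe set at 2894 ± 449 against 1588 ± 132 and 1630 ± 64.3, while the 18S probe set overlapped at 12392 ± 4283 against 8863 ± 611 and 10293 ± 4345 (SD, n = 3), differences that were not tested. The log2 changes of both mutants had a covariance of 0.0961 across probe sets (r = 0.597), where the simulated unchanged groups gave at most 0.0235 (r 0.519). With 1 WT array for 1 mutant and the other 2 for the other, in each of 6 ways chosen after seeing the data, the covariance was 0.0575 to 0.0775 (r 0.29 to 0.416), and 71 to 198 calls were shared in the same direction. The lone array was assumed to vary like the other groups. With 3 WT arrays no split leaves 2 for each mutant, and part of the excess of shared calls may come from the shared WT arrays. The number of shared calls was 204 without WT root replicate 1 and 331 without WT root replicate 3.

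**Figure D2:**
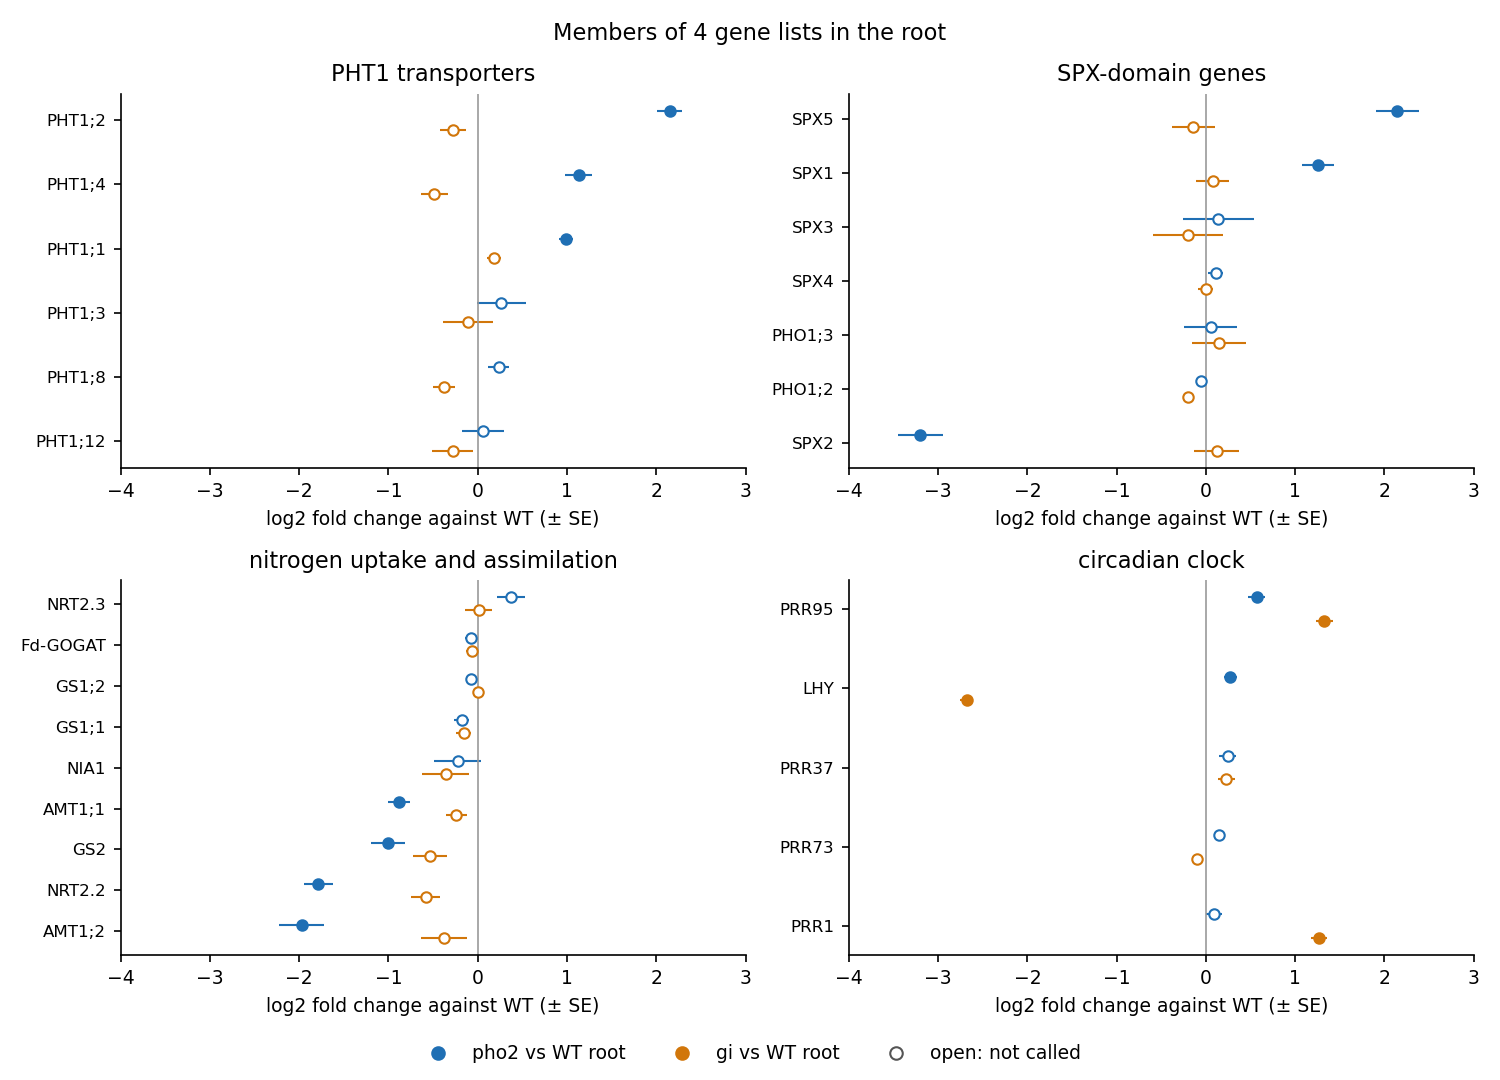
Log2 change against WT root with its standard error (x axis) for members of 4 gene lists, pho2 in blue and gi in orange, each from 3 arrays against 3, with filled points for called probe sets and open points for the rest. PHT1;2 lies at 2.15 in pho2 and -0.28 in gi, SPX2 at -3.20 and 0.12, AMT1;2 at -1.97 and -0.38, and LHY at 0.27 and -2.68.

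The highest named genes in pho2 shoots were LEA19, RAB21, JAZ11, Cht2, WRKY76 and PXG. LEA19, a late embryogenesis abundant protein, reached 2127 ± 1461 (SD, n = 3) against 2.51 ± 0.75 in WT (log2 change 6.46, SE 0.586, limma adjusted p = 1.06e-05), and RAB21, a dehydrin induced by abscisic acid, rose by 5.22 (SE 0.614, limma adjusted p = 6.73e-05). JAZ11, a jasmonate ZIM-domain repressor, rose by 4.83 (SE 0.431, limma adjusted p = 9.64e-06) and Cht2, a chitinase, by 4.54 (SE 0.308, limma adjusted p = 1.5e-06). WRKY76, a transcription factor of the defence response, reached 3027 ± 384 against 121 ± 29.7 (4.49, SE 0.201, limma adjusted p = 6.2e-08), and PXG, named for peroxygenase, rose by 4.45 (SE 0.363, limma adjusted p = 5.27e-06). Of 6 LEA genes, 5 rose and 0 fell, RAB16B by 3.38 (1.97 with a pseudocount of 64) and Dhn1 by 1.58 (camera adjusted p = 0.103, 0.0246 after median centring, and adjusted p = 0.525 with an estimated correlation). Of 6 WRKY factors 4 rose and 1 fell, WRKY62 by 3.39 and WRKY24 by 1.40 (camera adjusted p = 0.103, 0.0448 after median centring, and adjusted p = 0.525 with an estimated correlation). Of 28 jasmonate genes 13 rose and 6 fell, or 14 and 8 when adjusted over the list alone (camera adjusted p = 0.155). Among them JAZ12 rose by 3.16 (limma adjusted p = 6.08e-06) and OPR10 by 3.49, while COI1B, of the jasmonate receptor family, dropped by 0.87 (limma adjusted p = 8.93e-06). Of 11 defence genes 4 rose and 3 fell, CH16 by 4.22 (limma adjusted p = 1.03e-05), while Cht6 dropped by 1.1. Their median was -0.30, their mean 0.85 and the camera direction up (camera adjusted p = 0.953). Of 20 heat shock proteins 9 rose and 1 fell, HSP24.1 by 1.87 and HSP26.2 by 1.72 (limma adjusted p = 0.000217). Of 23 ribosomal proteins 18 rose and 0 fell, for example RPL5A by 0.51 (camera adjusted p = 7.11e-05, but adjusted p = 0.485 with an estimated correlation). CL18, a synonym of RPL18, rose by 0.91. Its WT signal was 704 ± 68.5 in root and 2953 ± 197 in shoot, and that of CL27, a synonym of RPL27, 434 ± 76.5 and 6237 ± 297 (SD, n = 3). The tables do not say whether either belongs to cytosolic or plastid ribosomes. The number of ribosomal proteins called higher was 23 after quantile normalization and 9 after median centring. Counts adjusted over the list alone were the same for the LEA, WRKY, defence and ribosomal lists, and 9 and 2 for heat shock proteins.

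The lowest named genes in pho2 shoots came from several families. BURP2, of the BURP domain family, dropped by 2.97 (SE 0.163, limma adjusted p = 3.18e-07), TUB6, a beta-tubulin, by 2.34 (SE 0.114, limma adjusted p = 1.18e-07) and GLT2 by 2.32 (SE 0.16, limma adjusted p = 1.71e-06). PBZ1, a pathogenesis-related protein of the PR10 family, dropped by 2.29 (SE 0.218, limma adjusted p = 1.48e-05), KIN14K, a kinesin, by 2.18 (limma adjusted p = 7.73e-05) and MTP4, of the metal tolerance protein family, by 2.09 (limma adjusted p = 1.81e-06). Of 8 iron acquisition genes 0 rose and 3 fell, NAS3, a nicotianamine synthase, by 2.01 and IRT1 by 1.02 (limma adjusted p = 0.00432). NIA1, a nitrate reductase, dropped by 1.07 (limma adjusted p = 3.39e-06, or -0.71 after quantile normalization). Of 9 nitrogen genes 1 rose and 4 fell, or 2 and 5 when adjusted over the list alone, and the list median of -0.31 turned to 0.05 after quantile normalization. Of 8 photosynthesis genes 1 rose and 7 fell (camera adjusted p = 0.103), but after quantile normalization, which pulls the brightest probe sets together, 1 rose and 1 fell. PSAG dropped by 0.54 (limma adjusted p = 0.000831), while LP02, a subunit of the oxygen-evolving complex, changed by -0.46 as deposited (limma adjusted p = 0.00765) and by -0.07 after quantile normalization (0.307, in a range of 0.000833 to 0.307).

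Of the phosphate transporters in pho2 shoots, PHT1;8 was called. It rose from 618 ± 254 to 1729 ± 321 (1.54, SE 0.296, limma adjusted p = 0.00199), the only 1 of 4 PHT1 transporters called, whose list median was -0.02 and mean 0.27, with 1 lower after quantile normalization. Of 5 SPX domain genes 0 rose and 3 fell, SPX1 by 0.76 (limma adjusted p = 0.000478), SPX2 by 0.58 and SPX4 by 0.47. PHR2, the main activator of Pi starvation genes, dropped by 0.46 (limma adjusted p = 0.0017), as 1 of 2 called genes among 6 of Pi signalling, and 2 of 4 starvation response genes fell. Of 7 clock genes 2 rose and 4 fell. PCL1, a LUX-type MYB factor, rose by 3.51 (SE 0.466, limma adjusted p = 0.000157) and PRR1 by 0.67, while LHY dropped by 0.51 (limma adjusted p = 0.000177) and PRR37 by 0.48, and the median of -0.45 and the mean of 0.25 differed in sign (camera adjusted p = 0.304). Of 11 flowering genes 0 rose and 4 fell, MADS18 by 1.63 (limma adjusted p = 4.11e-05) and MADS50, a SOC1-like activator of flowering, by 0.97 (limma adjusted p = 0.000128). Of 23 aquaporins 7 rose and 7 fell, with a median of -0.04 and a mean of 0.23, and 8 rose and 4 fell after quantile normalization, where the median was 0.13. Of 13 histone and replication genes 5 fell, of 20 starch and sucrose genes 5 rose and 3 fell (2 and 2 after median centring), and of 5 glycerolipid genes 1 rose and 1 fell (1 and 0 after quantile normalization). TPP7, a trehalose phosphate phosphatase, dropped by 1.22 and H2B.6, a histone, by 0.71. Of 4 diterpenoid genes 0 were called (limma), but 1 fell after either scaling, and 1 of 2 peroxidases rose. Counts higher and lower adjusted over the list alone were 1 and 4 for flowering, 0 and 3 for Pi signalling and 7 and 8 for aquaporins.

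Of 34355 probe sets, 9835 (28.6%) were called in pho2 shoots, 4950 higher and 4885 lower, and of the 2806 that changed by at least 2-fold 2026 were higher. The arrays of the groups were fully apart for 43.5% of the probe sets tested, where chance gives 10%. Root markers differed between these groups, with 2 of 6 higher and 2 lower, or 3 and 2 when adjusted over the list alone, PIP2;5 by 1.40 (limma adjusted p = 0.00376) and Lsi1, a silicon influx channel, by -1.27. The 3'/5' log2 ratio of actin was 3.53 ± 0.16 in pho2 shoot and 2.90 ± 0.19 in WT shoot (SD, n = 3), while that of GAPDH went the other way, at 1.90 ± 0.24 and 2.61 ± 0.09. The geometric mean signal of the hybridisation controls was 2726 in pho2 shoot and 3834 in WT shoot, beside the called LEA, WRKY, heat shock, ribosomal protein and photosynthesis genes.

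Genes called in gi shoots included clock genes and cellulose synthases. BBD1 reached 2809 ± 394 (SD, n = 3) against 221 ± 33.4 in WT (3.58, SE 0.159, limma adjusted p = 8.42e-08). CHS, chalcone synthase of flavonoid synthesis, rose by 3.26 (SE 0.575, limma adjusted p = 0.00212), GER5, of the germin-like family, by 3.69 (SE 0.788, limma adjusted p = 0.00679), TUB8, a beta-tubulin, by 3.12 (SE 0.41, limma adjusted p = 0.000304) and APG8D by 3.07 (SE 0.276, limma adjusted p = 2.32e-05). VLN4, a villin that bundles actin, rose by 2.94 (limma adjusted p = 0.000614, 1.68 with a pseudocount of 64). The cellulose synthase genes CESA4, CESA3 and CESA8 rose by 2.73, 2.15 and 1.94 (limma adjusted p = 0.000268, 0.000273 and 0.000583). CESA3 lay at 3989 ± 1730 in gi shoot, 823 ± 106 in WT shoot and 12590 ± 675 in WT root. TUB8 lay at 812 ± 536, 64.7 ± 10.3 and 10880 ± 915. RSs2, also bright in WT root (17300), lay at 118 ± 54.5 in gi shoot and 63.5 ± 13.4 in WT shoot. Root tissue in the gi shoot samples was not tested. At the lower end lay NAAT1, an aminotransferase of phytosiderophore synthesis, from 2386 ± 1042 to 156 ± 42.2 (-3.72, SE 0.367, limma adjusted p = 4.48e-05), CM-LOX1 (-2.93, SE 0.572, limma adjusted p = 0.00396), BURP2 (-2.02, limma adjusted p = 1.01e-05), HAK1, a high-affinity potassium transporter (-1.90, limma adjusted p = 0.000233), and ZIP8, of the zinc transporter family (-1.68, limma adjusted p = 0.00295). LHY dropped from 12106 ± 431 to 5849 ± 194 (-1.05, SE 0.069, limma adjusted p = 2.23e-06), PRR1 rose by 1.40 (limma adjusted p = 3.43e-06) and PRR95 by 0.55 (limma adjusted p = 0.000568). Of 7 clock genes 2 rose and 2 fell, or 3 and 3 when adjusted over the list alone. These include GI, after median centring 2 rose and 3 fell, and the list was not called (camera adjusted p = 0.58).

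The defence and jasmonate lists were not called in gi shoots. Of 11 defence genes 5 rose, 0 fell and 6 were not called, or 6 rose when adjusted over the list alone (camera adjusted p = 0.0597, 0.012 after median centring, and adjusted p = 0.644 with an estimated correlation). Cht11 rose by 1.41 (limma adjusted p = 0.00527), CH16 by 1.75 (limma adjusted p = 0.00773) and PBZ1 by 1.27 (limma adjusted p = 0.00182, but 0.125 in a fit of all 18 arrays, 0.00116 to 0.125 over its alternatives). Of 28 jasmonate genes 12 rose and 4 fell, or 13 and 4 when adjusted over the list alone, and 8 rose after median centring (camera adjusted p = 0.117, and adjusted p = 0.742 with an estimated correlation). JAZ12 rose by 2.1 (limma adjusted p = 0.000225) and JAZ7 by 1.35, while COI1B dropped by 0.66 (limma adjusted p = 0.000129). WRKY76 rose by 2.07 (limma adjusted p = 4.1e-05) and WRKY62 by 1.77, and of 6 WRKY factors 2 rose and 1 fell. CPS2, a diterpene cyclase of phytoalexin synthesis, rose by 2.32 (limma adjusted p = 0.00211, but 0.0639 in a fit of all 18 arrays, 0.000304 to 0.0639 over its alternatives) as the only called gene of 4. Of 23 ribosomal proteins 6 rose and 0 fell (camera adjusted p = 0.00181, but adjusted p = 0.644 with an estimated correlation), CL18 by 1.31. CL27 was called higher by 0.42 (limma adjusted p = 0.0144, 0.00522 to 0.104 over its alternatives), but the call ended in 6 of 14 alternatives, in a fit of all 18 arrays, after median centring, and without WT shoot replicate 1 or 3 or gi shoot replicate 1 or 2 (0.0604, 0.0597, 0.0531 and 0.0664). Without CL18 and CL27, a list chosen after seeing the data, 4 of 21 rose (camera adjusted p = 0.0101, but adjusted p = 0.741 with an estimated correlation). After median centring 1 of 23 rose and the camera adjusted p was 0.106. Of 20 heat shock proteins 5 rose and 0 fell, or 7 and 1 when adjusted over the list alone and 3 and 1 after median centring. PSB28, a photosystem II assembly factor, rose by 1.16 and PSAG dropped by 0.45 among 8 photosynthesis genes. Of 6 LEA genes 1 rose, RAB16C by 1.20 (limma adjusted p = 0.00665, but 0.152 in a fit of all 18 arrays, 0.00239 to 0.152 over its alternatives).

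Phosphate transcripts that were called in gi shoots fell. SPX4, which restrains PHR2, dropped by 0.46 (limma adjusted p = 0.0126, 0.00291 to 0.065 over its alternatives, ended without WT shoot replicate 3) and SPX1 by 0.45 (limma adjusted p = 0.0194, 0.00973 to 0.0935, ended in 5). PHO1;3 dropped by 0.64 (limma adjusted p = 0.0115, 0.0113 to 0.0764), a call that ended without WT shoot replicate 1 (0.0617) and in a fit of all 18 arrays (0.0764). PHT1;1 dropped by 0.54 (limma adjusted p = 0.036, 0.00492 to 0.127, ended in 7) as 1 of 4 PHT1 transporters, whose median was 0.22. Of 5 SPX domain genes 3 fell, as did 2 of 6 Pi signalling genes and 1 of 4 starvation response genes, also when adjusted over the list alone except for 3 Pi signalling genes. IRT1 dropped by 0.92 (limma adjusted p = 0.0134, 0.00196 to 0.0608), a call that ended without WT shoot replicate 1 (0.0527) or replicate 3 (0.0608), and 2 of 8 iron acquisition genes fell. Of 9 nitrogen genes 2 fell, with a median of -0.03 and a mean of 0.10, but 1 rose and 1 fell after quantile normalization. Of 11 flowering genes 2 fell, MADS18 by 0.66 (limma adjusted p = 0.0236, 0.0109 to 0.102, ended in 4). Of 23 aquaporins 5 rose and 3 fell, TIP1 by -0.90 (limma adjusted p = 0.000406), and after median centring 2 rose and 4 fell. Of 20 starch and sucrose genes 4 rose and 4 fell (2 and 3 after median centring), TPP7 by -0.68 (limma adjusted p = 0.000192). Of 13 histone and replication genes 1 fell (0 after median centring), of 5 glycerolipid genes 1 rose, and of 6 root markers 2 rose and 1 fell, or 0 in either direction after quantile normalization. Of 2 peroxidases 0 were called (limma). Counts higher and lower adjusted over the list alone were 1 and 1 for PHT1 transporters and glycerolipid genes, 1 and 2 for nitrogen, 6 and 4 for aquaporins and 0 and 0 for histones and replication.

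In gi shoots 6027 of 34355 probe sets (17.5%) were called, 3085 higher and 2942 lower, and of the 1692 that changed by at least 2-fold 1250 were higher. The groups were fully apart for 34.6% of probe sets, where chance gives 10%. After median centring, which moved the median of all log2 changes from -0.01 to -0.12, 40.5% of calls were higher against 51.2% as deposited. The count was 3849 without WT shoot replicate 1. The array of gi shoot replicate 1 had the lowest mean correlation with its own group (0.9546), and without it 4749 probe sets were called.

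**Figure D3:**
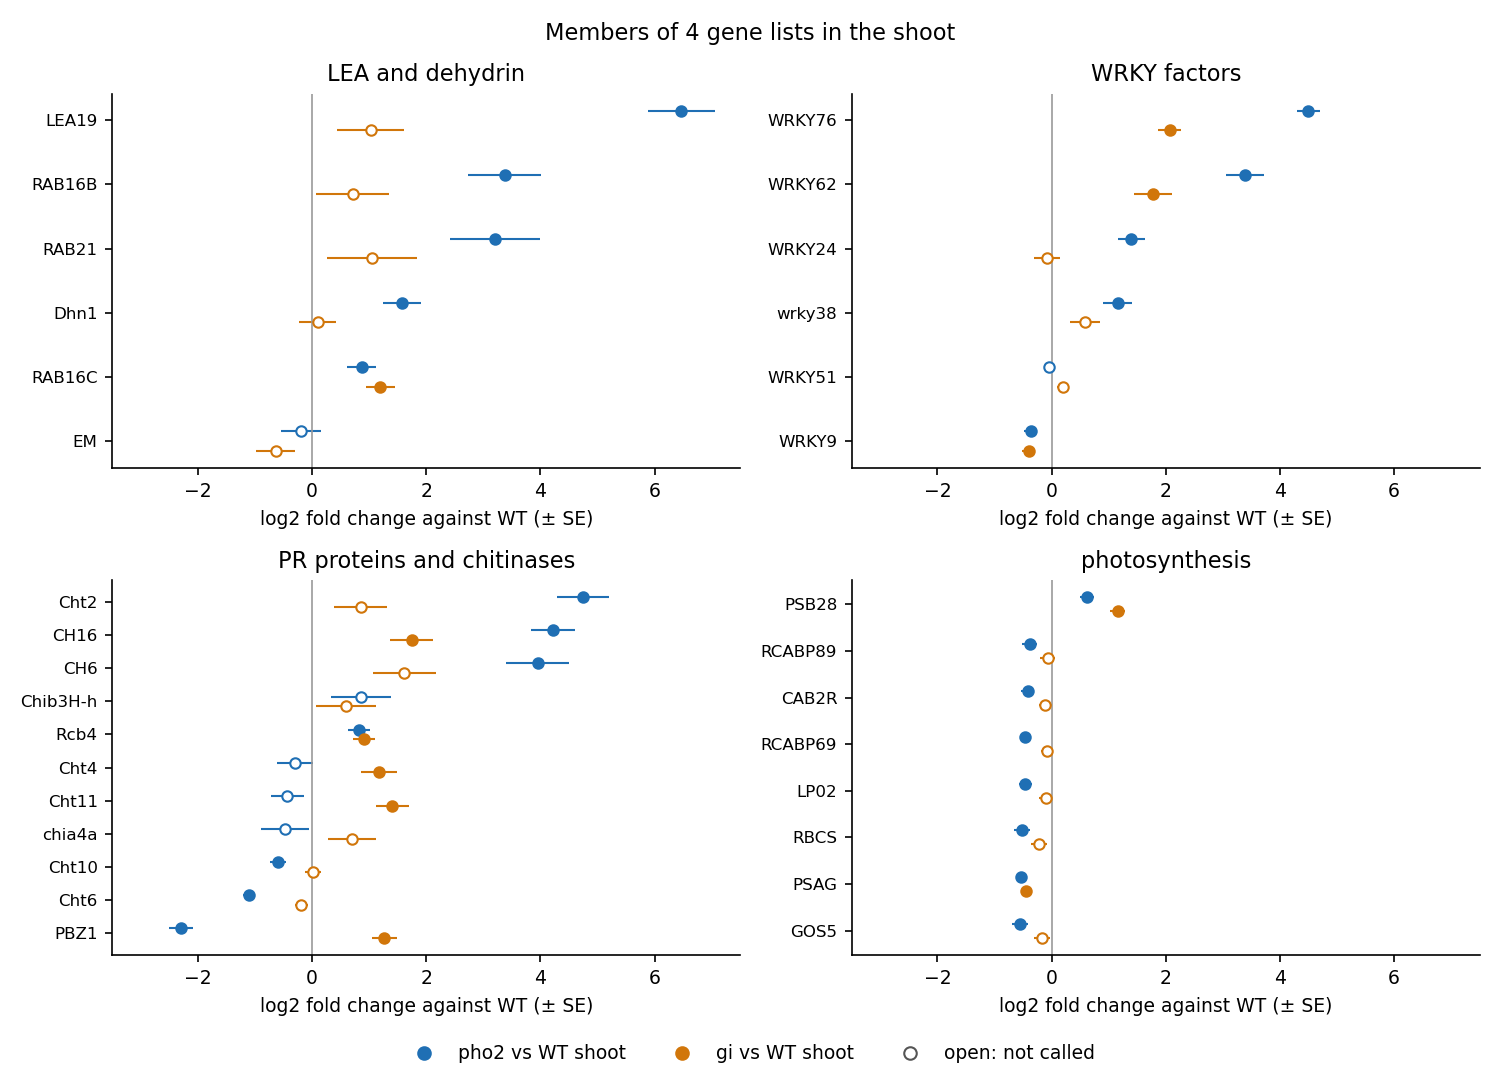
Log2 change against WT shoot with its standard error (x axis) for members of 4 gene lists, pho2 in blue and gi in orange, each from 3 arrays against 3, with filled points for called probe sets and open points for the rest. LEA19 lies at 6.46 in pho2 and 1.03 in gi, WRKY76 at 4.49 and 2.07, PBZ1 at -2.29 and 1.27, and of 8 photosynthesis genes 7 lie lower in pho2, where 1 is called lower after quantile normalization.

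Shoot changes were also shared between the mutants. GER5 rose by 3.56 in pho2 and 3.69 in gi, CHS by 3.17 and 3.26, TUB8 by 3.31 and 3.12, APG8D by 2.59 and 3.07, and PXG by 4.45 and 2.78 (1.79 in gi with a pseudocount of 64). Of the 6027 probe sets called in gi shoots, 3763 (62.4%) were called in pho2 shoots in the same direction, where independent lists would share 862.8, and 183 in the opposite direction. With pho2 as the common reference, WT and gi shoots shared 4159 calls in the same direction and 261 in the opposite. With gi as the reference, WT and pho2 shoots shared 1478 and 701. PBZ1 fell in pho2 (-2.29) and rose in gi (1.27), and OrysaZxb changed by -0.93 and 0.82. HAK1, by 1 of its probe sets, was 0.91 in pho2, where its call (limma adjusted p = 0.0303, 0.00215 to 0.122) ended in 5 alternatives, and -1.39 in gi. The covariance of the log2 changes was 0.2504 (r = 0.608), where simulated unchanged groups against the WT arrays gave at most 0.0456 (r 0.512). In the 6 splits of the WT arrays it was 0.198 to 0.214 (r 0.432 to 0.457), with 1147 to 1875 shared calls. Without WT shoot replicate 1 the mutants shared 2364 calls.

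In the comparison of the mutants in shoot, LEA19 was higher in pho2 than in gi by 5.44 (limma adjusted p = 8.49e-05), STLP3 by 3.92 (limma adjusted p = 3.15e-05) and Cht2 by 3.77 (limma adjusted p = 1.11e-05). PBZ1 changed by -3.56 (limma adjusted p = 1.78e-06), CPS2 by -3.46 (limma adjusted p = 0.000155), KS6, named for kaurene synthases, by -2.94 (limma adjusted p = 0.00121) and CYP71Z6, a cytochrome P450, by -2.62 (limma adjusted p = 7.9e-06). In total 6519 probe sets (19%) were called, 3354 higher and 3165 lower in pho2, 1654 by at least 2-fold. Without pho2 shoot replicate 1 the count was 4338. Of 18 lists tested 0 were called (camera), and 6 had an unadjusted p under 0.05.

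**Figure D4:**
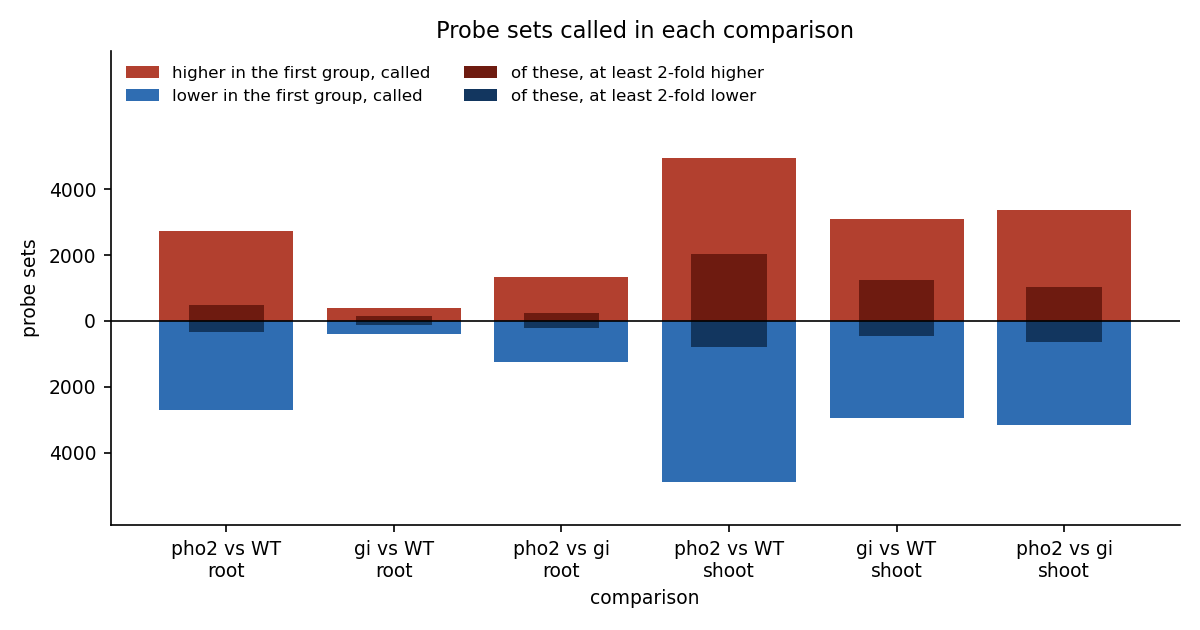
Number of probe sets called higher and lower (y axis, limma with Benjamini-Hochberg adjustment) in 6 comparisons, with the inner dark bars for changes of at least 2-fold. Called probe sets number 5438 for pho2 and 782 for gi against WT in root, and 9835 and 6027 in shoot.

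The effect of each mutation was compared between tissues with an interaction term. For pho2, the effect in root less that in shoot was 1.92 for PHT1;2 (limma adjusted p = 7.8e-05), 1.41 for PHT1;1 (limma adjusted p = 3.42e-05), 2.01 for SPX1 (limma adjusted p = 7.9e-06) and -2.62 for SPX2 (limma adjusted p = 6.38e-06). It was 2.77 for IRT1, which rose in root and fell in shoot, -4.09 for WRKY76 and 0.13 for OPR10 (limma adjusted p = 0.876). PHT1;2 was dim in shoot, at 42.7 to 49.9 on the WT arrays and 39.2 to 93.1 on the pho2 arrays. With signals this low, the pho2 effect on PHT1;2 in shoot was poorly measured. For gi, the effect differed for LHY by -1.63 (limma adjusted p = 3.26e-08), for IRT1 by 2.40, for SAPK9 by 1.23 (limma adjusted p = 0.00272) and for PRR95 by 0.77 (limma adjusted p = 0.000638), whereas BBD1 (-0.07, limma adjusted p = 0.899) and PRR1 (-0.14, limma adjusted p = 0.557) were not called. In total 9973 probe sets (29%) had a different pho2 effect in root and shoot, 4853 with the higher value in root, and 4198 (12.2%) a different gi effect, 2177 with the higher value in root. Between WT root and WT shoot themselves, 24381 probe sets (71%) were called, 13448 higher and 10933 lower in root, and quantile normalization moved the median of all log2 differences from 0.09 to -0.02.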

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

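None of the tests in this part was chosen after its result was seen. Groups of 3 arrays were not tested for single outlying arrays, so the results here are differences of a mutant's effect between tissues, and signals of control probe sets that enter no comparison.

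The pho2 effect differed between root and shoot for 9973 probe sets, by a test of the interaction (limma with Benjamini-Hochberg adjustment). Among 100 drawn splits of the arrays within tissues, 1, the real one, gave as many, a share under 0.05, and the highest other gave 6140. The split with the labels turned in 1 tissue was not drawn. The gi effect differed for 4198 probe sets. There 2 of 100 drawn splits gave as many, also a share under 0.05. They were the real split and the split with the labels turned in 1 tissue, which gave 4619 and keeps the real groups together. The other drawn splits mix mutant and WT arrays, which widens the spread and lowers the calls once a mutant has any effect. The shares therefore argue against arrays grouped at random, and do not test an equal effect in both tissues. Whether root and shoot samples were hybridised apart is not given in the sources used here.

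Among named genes, the pho2 effect in root less that in shoot was 2.77 for IRT1, 2.73 for BURP2, 2.71 for SPX5 and 2.69 for PBZ1. The SPX5 value was 1.77 with a pseudocount of 64. The PBZ1 call (limma adjusted p = 0.0183, 0.00667 to 0.0543 over its alternatives) ended without WT root replicate 1 (0.0526) or pho2 root replicate 3 (0.0543). At the other end lay LEA19 (-6.93), STLP3 (-5.33), RAB21 (-5.26) and JAZ11 (-4.43), with signals in pho2 shoot of 2127 ± 1461, 587.5 ± 225, 911.3 ± 530 and 2609 ± 1560 against 2.51 ± 0.754, 14.0 ± 3.91, 5.26 ± 2.25 and 64.4 ± 19.0 in WT shoot (SD, n = 3). Signals this low make the log2 values depend on the pseudocount.

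For gi, the difference between tissues was 4.53 for CM-LOX1, which rose in gi root (1.60) and fell in gi shoot (-2.93), 3.77 for NAAT1, 2.42 for GLO1 and 2.40 for IRT1. It was -3.74 for GER5, -3.41 for TUB8, -3.18 for CHS and -3.01 for VIT1.2. The GLO1 call (limma adjusted p = 0.0282, 0.00717 to 0.074) ended in 5 of 16 alternatives, among them without WT root replicate 1 (0.074). The GER5 call (0.019, 0.00073 to 0.0535) ended without WT shoot replicate 3 (0.0529) or gi shoot replicate 2 (0.0535). The VIT1.2 call (0.0206, 0.0151 to 0.0588) ended in 3, among them without gi root replicate 3 (0.0588).

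The 9 hybridisation control probe sets, which report RNA added to each sample and not rice transcripts, had a geometric mean signal in WT shoot 4.48 times that in WT root, and in pho2 shoot 0.711 times that in WT shoot. The first value pools unlike differences. The BioB probe sets (3, 5 and M) were dim in WT root, at 34.3, 48.2 and 51.1, against 982, 926 and 832 in WT shoot. The brighter controls differed less, with BioC-3 at 986 in WT root and 2249 in WT shoot, BioDn-3 at 5241 and 9416, and CreX-3 at 14667 and 28742. Tissue and hybridisation batch cannot be told apart here.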

How the results depend on the processing

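Of the alternatives, the splits of WT 1 and 2 between the mutants, the ribosomal list without CL18 and CL27 and GI in pho2 with 6 arrays were chosen after seeing the data. Of the recomputed log2 changes of named genes, 4786 kept their direction and their side of the threshold, 406 no longer passed it, 20 newly passed it and 2 reversed. Of the recomputed tests of the 7 lists called as deposited against WT, 71 remained called and 9 did not. Outside these counts are lists not called as deposited, lists called for pho2 against gi, and median centring. After median centring the clock list in pho2 root and the ribosomal list in gi shoot were not called, nor was the starvation response list for pho2 against gi in root. The reversed gene values were those of SPX5 in gi root, which was not called (-0.14), at 0.076 without gi root replicate 1 and 0.019 without WT root replicate 1, the lowest being -0.293 without gi root replicate 2. Named calls of pho2 against gi held under every alternative run (8 of 8 in root and 8 of 8 in shoot), as did 43 of 75 named calls for pho2 root, 14 of 30 for gi root, 99 of 107 for pho2 shoot, 56 of 86 for gi shoot, and 7 of 8 and 5 of 8 for the pho2 and gi tissue differences. Arrays give no depth, and signal near background limits the dim probe sets. The planned split of WT with at least 2 arrays for each mutant was not run, since WT has 3. In the 6 splits of 1 and 2 arrays, where fewer arrays enter each comparison, shared calls numbered 71 to 198 in root and 1147 to 1875 in shoot. Without CL18 and CL27, the ribosomal list was called with camera adjusted p = 7.86e-07 in pho2 root, 0.00015 in pho2 shoot and 0.0101 in gi shoot, but had adjusted p = 0.394, 0.485 and 0.741 with an estimated correlation, where none was called. A size minimum lowers counts by construction, and for the other changes the cause was not tested.

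With a 2-fold minimum, calls numbered 820 (pho2 root), 281 (gi root), 433 (pho2 against gi, root), 2806 (pho2 shoot), 1692 (gi shoot) and 1654 (pho2 against gi, shoot). Without an intensity trend they numbered 410 (gi root), 1194 (pho2 against gi, root), 3965 (gi shoot) and 4243 (pho2 against gi, shoot). Median centring gave 1392 and 4233 for pho2 against gi in root and shoot, and a fit of all 18 arrays gave 1677 in root. With no filter, the shared root calls numbered 344 and gi root had 1 list called. Over the 4 mutant and WT comparisons, list calls numbered 0 with an estimated correlation, for pho2 root, pho2 shoot, gi shoot and in total. They numbered 9 for pho2 root, 1 for gi root and 12 in total after quantile normalization, and 7, 3 and 12 with the mean of a gene's probe sets.

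Without each array in turn, calls ranged from 3385 to 4139 (pho2 root), 313 to 560 (gi root), 1071 to 2202 (pho2 against gi, root), 7478 to 9273 (pho2 shoot), 3849 to 6238 (gi shoot), 4338 to 6688 (pho2 against gi, shoot), 8867 to 9925 and 2971 to 4893 (pho2 and gi tissue differences) and 23135 to 23525 (WT root against shoot). Shared calls, recomputed only without each of the 3 WT arrays of a tissue, ranged from 204 to 394 in root and 2364 to 3076 in shoot. List calls ranged from 4 to 8 (pho2 root), 0 to 2 (gi root), 1 to 3 (pho2 shoot), 1 to 3 (gi shoot) and 6 to 10 in total.

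Replicate numbers did not pair the samples. Deviations from the group mean of arrays with the same number correlated at -0.102 to 0.12 over 18 pairs within a tissue, and only for gi root and pho2 root did all 3 numbers correlate best with their own. With the replicate block, calls numbered 4778 (pho2 root), 649 (gi root), 2005 (pho2 against gi, root), 9255 (pho2 shoot), 5399 (gi shoot), 5836 (pho2 against gi, shoot), 10369 and 4575 (tissue differences) and 24611 (WT root against shoot), and shared calls 434 and 3417. List calls with the block numbered 7 for pho2 root, 2 for gi root, 2 for gi shoot and 12 in total.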

Other observations

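The splits of the arrays for the 6 counts of calls between genotypes, the splits of WT 1 and 2 between the mutants, the counts with pho2 or gi as the reference and the test of WT growth or handling were chosen only after the results were seen, and the 7 lists of the next paragraphs were added before their own values were seen. In gi shoot, expansins and cellulose synthases, which loosen and build cell walls, stood higher than other genes (camera adjusted p = 0.00589, and adjusted p = 0.787 with an estimated correlation). Of 28 genes tested, 10 rose and 1 fell over all probe sets, and 13 and 1 adjusted over the list alone. EXPB3 rose by 2.59 on the log2 scale (limma adjusted p = 0.00086). In pho2 shoot the same list had 13 genes higher and 2 lower, 15 and 2 adjusted over the list alone, and was not called (camera adjusted p = 0.054, 0.00797 with median centring, and adjusted p = 0.68 with an estimated correlation). CESA1 rose by 1.89 (limma adjusted p = 0.00187) and CESA3 by 1.68 (limma adjusted p = 0.000709). In pho2 root it had 2 higher and 8 lower of 34, and 3 and 9 adjusted over the list alone (0 and 7 with median centring), and in gi root 0 and 0. Genes of protein folding in the endoplasmic reticulum, which fold secreted proteins, stood higher in pho2 shoot than in gi shoot (camera adjusted p = 0.00215, and adjusted p = 0.766 with an estimated correlation). Of 17 genes, 9 were higher and 0 lower in that comparison, and 10 and 0 adjusted over the list alone. Against WT, 8 rose and 0 fell in pho2 shoot (camera adjusted p = 0.054), among them PDI (0.63, limma adjusted p = 0.000398) and CRO1 (0.68, limma adjusted p = 0.000558). In gi shoot 0 rose and 2 fell, in pho2 root 0 and 3 (0 and 1 with median centring), and in gi root 0 and 0, and these counts did not change adjusted over the list alone.

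Metal transporters had 4 genes higher and 10 lower of 31 in pho2 shoot and 1 higher and 8 lower in gi shoot, the same counts adjusted over the list alone. NRAMP4 fell in both (-1.58 in pho2, limma adjusted p = 4.31e-05, and -1.16 in gi, limma adjusted p = 0.000738), and YSL9 fell in pho2 shoot (-1.12, limma adjusted p = 3.06e-05). In pho2 root 8 of 30 were higher and 3 lower, 9 and 3 adjusted over the list alone (3 and 2 with median centring), with YSL13 at 1.51 (limma adjusted p = 0.000541). In gi root the counts were 1 and 2, and 2 and 4 adjusted over the list alone. Auxin genes had 4 higher and 11 lower of 34 in pho2 shoot, 4 and 14 adjusted over the list alone, with PIN5A, an auxin carrier, at -1.06 (limma adjusted p = 2.25e-05). They had 3 and 5 in gi shoot, 4 and 1 of 42 in pho2 root and 0 and 1 in gi root, and 4 and 6, 7 and 1, and 0 and 1 adjusted over the list alone. In gi shoot their median was 0.01, while camera's direction was down. Sugar transporters had 0 higher and 4 lower of 14 in pho2 root (0 and 2 with median centring), where SWEET1A fell by 1.71 on the log2 scale (825 ± 263 against 2659 ± 428, SD, n = 3, limma adjusted p = 0.00123). They had 0 and 0 in gi root, 4 and 2 of 12 in pho2 shoot and 2 and 0 in gi shoot, the last being 3 and 1 adjusted over the list alone. Potassium transporters of the HAK family had 2 and 0 of 18 in pho2 root, 2 and 1 in gi root, 4 and 4 of 19 in pho2 shoot and 3 and 3 in gi shoot, and 6 and 1, 4 and 3, 5 and 4, and 3 and 3 adjusted over the list alone. HAK23 fell in pho2 shoot (-0.99, limma adjusted p = 3.69e-05) and in gi shoot (-1.11, limma adjusted p = 3.82e-05). Cell cycle genes had 4 and 1 of 24 in pho2 root (2 and 2 with median centring), 0 and 0 in gi root, 1 and 2 of 21 in pho2 shoot and 3 and 0 in gi shoot, the same adjusted over the list alone. Median, mean and camera direction differed in sign for cell cycle genes in pho2 root, for auxin, cell wall, HAK and sugar transport genes in gi root, for HAK genes in pho2 shoot, and for auxin and sugar transport genes in gi shoot. None of these 5 lists was called by camera against WT in either tissue.

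The pho2 shoot arrays lay closer to the WT root arrays than the WT shoot arrays did, with mean Spearman correlations of 0.7756 (0.7676 to 0.7808) against 0.7471 (0.7433 to 0.7523), and 0.7506 (0.7281 to 0.7634) for gi shoot. A scaling factor per array cannot move a rank correlation, and the lowest pho2 array lay 0.0153 above the highest WT shoot array, which argues against such a factor as the cause. Other technical differences, as of labelling or RNA quality, were not tested. The hybridisation controls lay at 2726 in pho2 shoot, between 3834 in WT shoot and 855 in WT root. The 3'/5' log2 ratio of GAPDH also lay between (1.90, against 2.61 and 1.69), but that of actin did not (3.53, against 2.90 and 2.79). Root tissue mixed into the pho2 shoot samples would need a share of 1.96% of root signal, and of 604 probe sets bright in WT root (at least 1000) and dim in WT shoot (at most 50), 56.0% lay under 50% of that share, past the bound of 50% set beforehand. That bound left open which probe sets to take, and over 15 definitions, 14 of them tried after the first result, the value ran from 45.5% to 75.5% with 13 at or above the bound, so the outcome depends on the choice and root tissue stays open. The median share ran from 0.25% to 1.27% over the 15 definitions, under the needed 1.96%, but 28.3% of the 604 probe sets lay over it. A change within pho2 shoots was not tested.

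The pho2 and gi effects against WT varied together in both tissues. The observed covariance of their log2 changes was at least 4.09 times the highest of 100 simulated ones for unchanged groups against those arrays, and with WT split 1 and 2 between the mutants it was still 0.0575 to 0.0775 in root and 0.198 to 0.214 in shoot, which argues against chance values of the shared WT arrays as the whole cause. Of 100 drawn splits into 3 groups, 2 called as many probe sets in the same direction as the real 518 in root and 2 as many as the real 3763 in shoot, a share under 0.05 in both tissues. In root the other split was a grouping that is not the genotypes, with 1166 calls, above the real count, for a reason that was not tested. The real groups with pho2 as the reference, which were not drawn in root, gave 1762 there. In shoot the highest other, 4159, was the real groups with pho2 as the reference. The count is taken against the reference group and was higher in both tissues with pho2 than with WT as the reference. The share therefore does not decide whether pho2 and gi share more calls than chance gives. A difference of the WT samples from both mutants in growth or handling stays open. Affymetrix controls for added RNA, which were not tested, also set WT shoot apart. DapX-3 lay at 6037 ± 104 in WT shoot against 4543 ± 129 in gi and 3827 ± 396 in pho2 (SD, n = 3). LysX-3 lay at 1151 ± 64.9 against 834 ± 62.9 and 736 ± 11.1. In root, the mean of DapX-3 was lower in WT, at 2938 ± 141 against 3330 ± 228 in gi and 3361 ± 375 in pho2. Calls of pho2 against gi were at least 1.08 times those of gi against WT in both tissues, which would also be seen if part of the shift lay in the WT samples. Ribosomal RNA signals were not tested. In root, both mutants lay lower for 28S, at 9301 in WT against 4903 in gi and 5705 in pho2. The same held for 25S (2894 against 1588 and 1630) and 5.8S (181 against 136 and 133). In shoot, both mutants lay higher for 28S (3445 ± 34.4 in WT against 3941 ± 715 in gi and 4519 ± 214 in pho2, SD, n = 3) and 5.8S (47.4 against 85.8 and 129). There 25S was divided, at 773 against 583 and 1580.2. The mean of 18S was lower in both mutants, at 19864 ± 281 in WT shoot against 15809 ± 3713 in gi and 10995 ± 4569 in pho2. A shared effect of losing either gene may also account for the shared changes and was not tested apart.

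The 6 arrays of a comparison make 10 splits, too few for a share under 0.05. In each case 1 split, the real one, gave as many calls, with 0 in the highest other, for pho2 root (5438), gi root (782), pho2 against gi in root (2591), pho2 shoot (9835), gi shoot (6027), pho2 against gi in shoot (6519) and WT root against shoot (24381). As many gene lists were called by 4 of the splits in pho2 root (real 4, highest other 5), 10 in gi root (0 and 3), 7 in pho2 shoot (1 and 4) and 7 in gi shoot (1 and 5). In gi root, 7 lists had an unadjusted camera p under 0.05.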
